A study of Mus musculus with 6 samples.

How the data were processed

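Gene expression was measured by RNA sequencing in organoids, 3-dimensional cultures grown from mouse colon tumour cells in a basement membrane gel. Per the labels, the tumour cells lacked functional Apc and Trp53 and carried 1 Kras G12D allele with the other allele deleted. The organoids received 10 µM bethanechol, an agonist of muscarinic acetylcholine receptors, or vehicle for 24 h in medium with 0.5% fetal bovine serum. Each group held 3 libraries, which the series description calls independent replicates. The labels do not tie a library to a culture, passage or day, so the p-values measure the spread between these samples, which may be partly technical.

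Per the labels' protocols, total RNA was selected for poly-A transcripts, made into Illumina TruSeq libraries and sequenced on an Illumina NovaSeq as paired-end reads of 100 bp. Per the submitters' processing notes, bcl2fastq 2.19 and kallisto 0.44.0 were used with mouse build GRCm38.p6. The annotation release, any use of strand in counting and any filter on reads are not given in the sources used here. The authors deposited a table of kallisto estimated counts per gene symbol, written as whole numbers and not normalized. The authors also deposited a table of TPM (transcript abundance scaled to a common total), in which each library summed to between 999654 and 999886. Both tables held 35764 symbols in 6 libraries, and every column matched a library name in the labels.

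kallisto assigns a read that fits several transcripts by estimation. Counts of genes with near-identical copies, such as Gsta1, the Ifi200 family, the class I and class II histocompatibility genes and genes with many pseudogenes, are therefore uncertain. Genes that overlap on opposite strands may share reads.

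Total estimated counts per library ranged from 35747505 to 49197886. A count of 3 in a library, the upper limit that a count of 0 allows, corresponded to between 0.0568 and 0.0832 CPM, counts scaled to a common library size. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

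The estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by the trimmed mean of M values (TMM), low genes were removed with filterByExpr at its minimum count of 10, and bethanechol was compared with vehicle by edgeR's quasi-likelihood test. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. CPM values are TMM-scaled. A log2 fold change is bethanechol over vehicle, and fitted values of genes near 0 counts depend on the prior count. For a gene with 0 counts in all 3 vehicle libraries, the fold is therefore given as a lower bound against 3 counts per library. For a gene with 1 to 3 vehicle counts in all, the ratio is given with its 95% counting interval.

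Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 38 lists with at least 5 tested members. The same test was run with the correlation estimated for each list. That form also takes its p-values on the few residual degrees of freedom of the 6 libraries. Members were also counted with p-values adjusted over the list alone. The lists covered cholinergic genes, signalling, stem and differentiated cell markers, immune genes, metabolism, stress, cell cycle and markers of 6 cell types. The named genes followed a rule. It took the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 1 CPM and no overlap between groups, leaving out predicted genes and pseudogenes. It added the 10 smallest p-values, the muscarinic receptors, Apc, Kras, Trp53, and up to 4 members per list. The design, lists, rule and most alternatives were fixed before the data were examined.

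Gene coordinates, biotypes and GC content came from GENCODE release M21 on GRCm38, matched by symbol for 15119 of the 15819 tested genes (95.6%). The scripts were tested on simulated counts drawn with the means, dispersions and library sizes of these libraries. Over 15413 simulated genes, 22.6% of genes changed by 1.5-fold, 70.1% of those changed by 2-fold and 92.2% of those changed by 4-fold were recovered, with 9 false calls. Among 38 simulated lists, the shifted list was called and 0 others were. The simulation drew genes independently of each other from a mean shared by both groups, and changed few of them. In these data most tested genes differed and list members may be correlated. The simulation therefore checked the scripts and not the error rates of the real calls.

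The alternatives were DESeq2 size factors, library totals, other filters, DESeq2 1.42.0, limma-voom, limma on log2 TPM with pseudocounts of 1 and 0.1, a replicate block, stricter thresholds and leaving out each library. Fits without 2 libraries that stood apart, with that division as a term, and with the close pairs of libraries summed were added after seeing the data. Over genes with at least 20 counts, the chi-square per gene was 3.78 between vehicle 1 and 2 and 2.3 between bethanechol 2 and 3, against 77.2 to 101 for the other pairs within a group. The 2 close pairs differed by more than counting noise and were counted as separate libraries, but they may be closer to technical repeats than to independent cultures, in which case each group holds fewer than 3 independent samples.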

Results

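The data were estimated counts of gene transcripts in 6 libraries from mouse colon tumour organoids, 3 treated with vehicle and 3 with bethanechol. The vehicle libraries held 39584731, 37897309 and 46008611 estimated counts, and the bethanechol libraries held 48401633, 35747505 and 49197886. At least 10 counts were found for 13474 ± 161 genes in the vehicle libraries and 16200 ± 295 genes in the bethanechol libraries (mean ± SD, n = 3 each). Mitochondrially encoded transcripts took 5.53%, 5.73% and 8.52% of the vehicle counts and 9.27%, 6.19% and 6.3% of the bethanechol counts.

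The design asked how 24 h of 10 µM bethanechol changed gene expression in organoids with altered Apc, Kras and Trp53. The labels do not tie both groups to the same culture or line. The differences given here are therefore between the groups and may not all be due to the drug. Genes of DNA replication and mitosis fell, as did Atf4 and other genes of the integrated stress response, while every measured gene of the cholesterol synthesis list rose. A large number of genes with few or no counts in vehicle libraries were expressed in bethanechol libraries, among them genes best known from neurons, endocrine cells and connective tissue, antigen presentation genes, and 3 muscarinic receptor genes. Mcm5, part of the replicative helicase, fell from 78.7 ± 2.78 to 6.99 ± 0.369 CPM, and Epcam, an epithelial adhesion gene, rose from 28.3 ± 1.72 to 353 ± 21.5 CPM (mean ± SD, n = 3 each). The keratin transcripts Krt8 and Krt18, which mark simple epithelia, did not pass the test, at 1007.5 and 690 CPM with vehicle and 1096 and 588 CPM with bethanechol.

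In edgeR's quasi-likelihood test, 12198 of 15819 genes (77.1%) passed a Benjamini-Hochberg adjusted p of 0.05, with 6548 higher and 5650 lower with bethanechol. The changes were uneven in size: 4902 genes rose and 1572 fell by more than 2-fold, and 3440 rose and 260 fell by more than 4-fold. The groups did not overlap for 12562 genes, or 79.4% of those tested, against 10% by chance with 3 libraries against 3. The biological coefficient of variation was 15.1%. The balance of directions differed between fits, with 53.7% of called genes higher here and 62.5% with edgeR on library totals. In limma on log2(TPM + 1), which differs in scaling, pseudocount and test, 7492 genes were higher and 3158 lower, or 70.3% higher. Scaling by library totals moved the median log2 fold change of tested genes from 0.08 to 0.27.

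**Figure D1:**
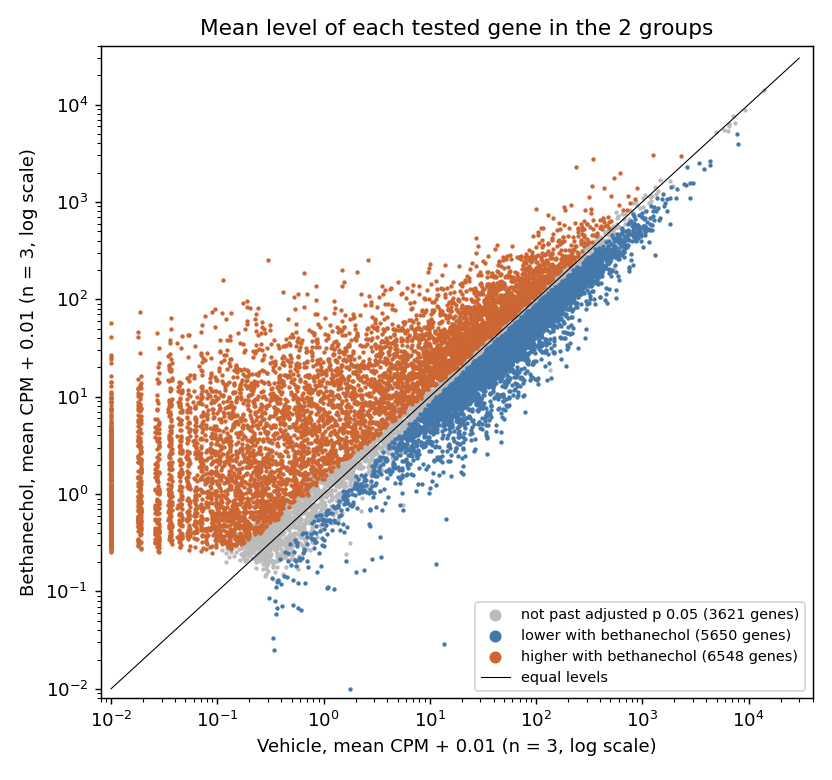
Mean CPM of each of the 15819 tested genes with vehicle (x axis) and bethanechol (y axis), n = 3 each, on log axes after adding 0.01; colours mark genes past an adjusted p of 0.05 and the line marks equal levels. Points at the left edge are genes with 0 or few vehicle counts, and they spread far above the line, whereas few genes lie at the lower edge.

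A total of 600 genes were under 0.1 CPM in all vehicle libraries and over 1 CPM in all bethanechol libraries, and 582 of them were annotated as protein-coding. The opposite pattern was seen for 1 gene, Gm3776, a predicted gene chosen after its values were seen and a near-identical relative of Gsta1. Of the 600 genes, 150 had 0 counts in all 3 vehicle libraries.

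The largest rises included genes with 0 counts in all vehicle libraries. Rcn3 (chromosome 7, 45082913 to 45092221), encoding a calcium-binding protein of the endoplasmic reticulum, reached 57.2 ± 4.61 CPM and was at least 729.5-fold higher (adjusted p = 1.1e-06). Pacsin1 (chromosome 17, 27655509 to 27711482), a neuronal endocytosis gene, was at least 523.8-fold higher, and Adcy5 (chromosome 16, 35154877 to 35305738), an adenylyl cyclase gene, was at least 340.3-fold higher. The synaptic gene Clstn3 was at least 322.4-fold, the cartilage proteoglycan gene Acan at least 312.7-fold, and the retinoid-binding gene Crabp1 at least 284-fold higher. Septin4, Fgf3, Sncb and the chromatin gene Satb1 were at least 208.9-, 180.8-, 180.6- and 162.3-fold higher. The collagen gene Col5a3 had 1 count in all vehicle libraries against 10470 with bethanechol, a ratio of 8480 (95% counting interval 1520 to 335000). The calcium channel gene Cacna1h also had 1 vehicle count, against 6545 with bethanechol (ratio 5300, interval 951 to 209000).

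The largest falls were smaller. Gsta1 (chromosome 9, 78230656 to 78242684), a glutathione transferase gene with near-identical copies, fell from 11.5 ± 0.986 to 0.184 ± 0.115 CPM, a log2 fold change of -5.92 (adjusted p = 3.8e-06). Bcl2l15 (chromosome 3, 103832601 to 103854618), an apoptosis-related gene, changed by -4.72 and the interferon-inducible Ifi207 by -3.99. The ATP receptor gene P2rx3 changed by -3.98 on the log2 scale, Cth, an enzyme gene of cysteine synthesis, by -3.77, Eps8l3 by -3.73 and Brd3os by -3.71. The other large falls were in genes of cell division (Kif15, -3.78; Ska1, -3.67; Esco2, -3.52; Mcm5, -3.49) and in the stress-response gene Ddit3 (-3.42).

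The 10 smallest p-values belonged to genes that rose. Scube3 went from 0.0784 ± 0.0056 to 73.8 ± 2.21 CPM (adjusted p = 1e-07), the lymphatic growth factor receptor gene Flt4 from 0.181 ± 0.0381 to 97.2 ± 1.66 CPM, and the axonal motor gene Kif1a from 1.49 ± 0.0914 to 199.7 ± 8.93 CPM. The collagen genes Col5a1 and Col6a1 rose by log2 fold changes of 5.65 and 6.55, and Atp1b1, a sodium pump subunit gene, by 5.16. Adam8, Tmod2 and Tmem132b rose by 5.04, 6.36 and 6.78. The synaptotagmin gene Syt1, the calcium sensor of synaptic vesicles, had 3 vehicle counts in all and 5493 bethanechol counts (ratio 1480, interval 507 to 7190).

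Bethanechol acts on muscarinic receptors, so their genes were examined next. In vehicle libraries they were at or near the floor, which averaged 0.0784 CPM. Chrm1 (chromosome 19, 8663789 to 8683587) rose from 0.0884 ± 0.035 to 2.57 ± 0.263 CPM, a log2 fold change of 4.84 (adjusted p = 6.7e-06), on 10 against 363 counts. Chrm4 (chromosome 2, 91927249 to 91928688) rose from 0.183 ± 0.0131 to 16.4 ± 0.626 CPM (log2 fold change 6.47, adjusted p = 1.4e-07), on 21 against 2338 counts. Chrm3 (chromosome 13, 9875486 to 10360847), a receptor coupled to Gq like Chrm1, had 2 vehicle and 192 bethanechol counts, a ratio of 77.8 with an interval of 21.2 to 647. Chrm2 had 0 vehicle and 25 bethanechol counts and Chrm5 had 0 and 2, and the filter on low counts left both out. In the fits that tested Chrm2 it was higher with bethanechol without the filter (adjusted p = 0.00448), with DESeq2 (0.00171), with close pairs of libraries summed (0.00836) and with log2(TPM + 1) without the filter (0.0402), while Chrm5 did not pass (0.299 without the filter, 0.39 with log2(TPM + 1) without the filter). Of the altered tumour genes, Trp53 transcripts fell by 0.44 on the log2 scale (adjusted p = 0.0024). This call was lost with log2(TPM + 0.1) (-0.28, adjusted p = 0.0509) and with log2(TPM + 1) without the filter (-0.26, 0.0648). Kras changed by 0.07 (adjusted p = 0.353), but passed at 0.26 with library totals (0.0034), at 0.55 with log2(TPM + 1) (0.00382), at 0.10 without vehicle 3 and bethanechol 1 (0.00204) and at 0.07 with the library set as a term (0.0413). The last 2 fits count the close pairs as separate libraries, and Kras did not pass with these pairs summed. Apc rose by 0.28 (adjusted p = 0.0328), which was lost without vehicle 1 (adjusted p = 0.133), vehicle 2 (0.117), bethanechol 1 (0.0803) or bethanechol 3 (0.078), with a replicate block (0.0641), with close pairs of libraries summed (0.198), without the filter on low counts (0.055) and against a minimum change of 1.2-fold (0.275).

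**Figure D2:**
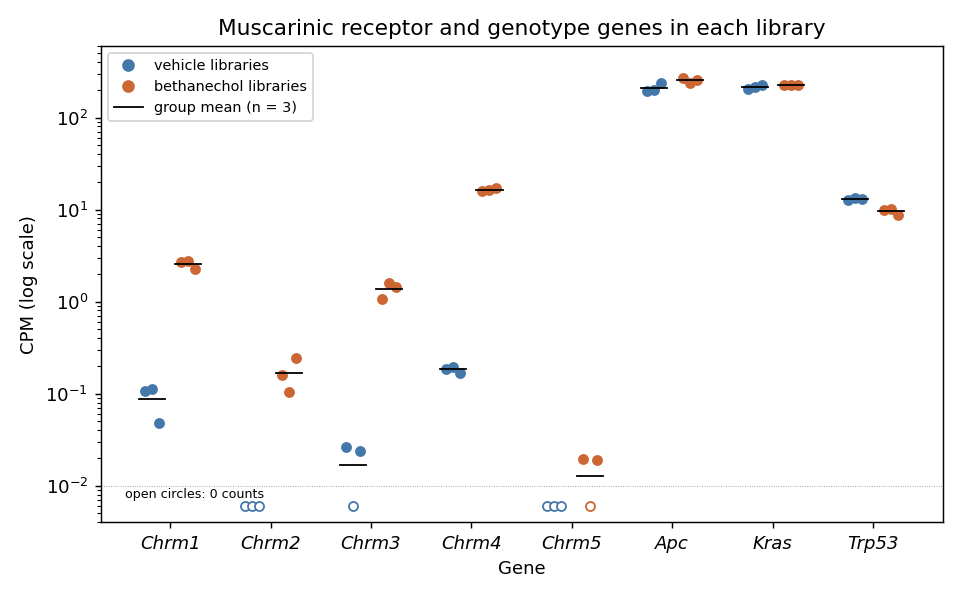
CPM of the 5 muscarinic receptor genes and of Apc, Kras and Trp53 in each of the 6 libraries on a log axis; filled points are libraries, open points are libraries with 0 counts, and bars are group means (n = 3). Chrm1, Chrm3 and Chrm4 were higher in all 3 bethanechol libraries than in any vehicle library, while Apc and Kras differed little between groups.

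Of the 38 gene lists, 21 passed an adjusted p of 0.05 in camera with the preset correlation, 17 higher and 4 lower. With a correlation estimated for each list, camera called 0 lists, and 8 had an unadjusted p under 0.05. Counts of changed members adjusted over the list alone were the same as those over all genes for 35 lists, and the other lists are given with both counts. A gene near the floor in vehicle libraries passed the filter only if bethanechol libraries expressed it. In lists of such genes, the share of tested members that rose, and with it the p-value of the list, is therefore partly set by the filter. Tested were 9 of 16 enteroendocrine, 11 of 16 tuft, 6 of 14 goblet, 9 of 13 leukocyte and 5 of 8 endothelial markers. So were 13 of 20 colonocyte, 11 of 12 fibroblast and 6 of 7 smooth muscle markers. Of the interferon-stimulated genes 20 of 25 were tested, and of the epithelial ion transport genes 15 of 19. Markers of other cell types rose with the same libraries as the rises described here: Col1a1 reached 80.1 ± 6.94 CPM, Uchl1 253 ± 12.5 CPM and H2-Ab1 31.8 ± 0.647 CPM.

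The lists of cell division fell. All 18 G1/S genes fell (median log2 fold change -2.39, adjusted p = 3.3e-08, and adjusted p = 0.0536 with an estimated correlation), including Mcm4 from 139 to 15.4 CPM, Mcm3 from 104 to 13.4 CPM and Mcm2 from 200.2 to 32.2 CPM. All 20 G2/M genes fell (median -2.25, adjusted p = 3.3e-08, and adjusted p = 0.0536 with an estimated correlation), including the mitotic motor Kif11 (-2.89), cyclin Ccna2 (-2.53), topoisomerase Top2a (-2.36) and Nusap1 (-2.15). All 15 genes of DNA damage and replication stress fell (adjusted p = 7.1e-07, and adjusted p = 0.205 with an estimated correlation), with Rad51 at -3.09, Exo1 at -3.11, Fancd2 at -3.07 and Chek1 at -2.92.

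In the unfolded protein and integrated stress response list, 15 of 21 genes fell, 3 rose and 3 did not pass (adjusted p = 0.0016, and adjusted p = 0.134 with an estimated correlation). Those that fell included Ddit3 from 46.9 to 4.37 CPM, Chac1 from 35.0 to 5.13 CPM, Sesn2 from 25.1 to 7.08 CPM and their activator Atf4 from 561 ± 45.5 to 104 ± 10.7 CPM. The cystine transporter gene Slc7a11, also in that list, rose by 0.94.

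All 21 cholesterol synthesis genes rose, by a median log2 fold change of 1.45 (adjusted p = 1.1e-05, and adjusted p = 0.205 with an estimated correlation). Dhcr24 rose by 1.91, Dhcr7 by 1.99, Nsdhl by 1.58 and Fdft1 by 1.43, and Ldlr, the lipoprotein receptor gene, by 2.47. The fatty acid list did not pass (adjusted p = 0.101, but 0.0435 with log2(TPM + 1) and 0.0499 with library totals), with 10 of 18 genes up and 2 down, or 1 down when adjusted over the list alone. Its desaturase gene Scd1 rose by 2.13, Scd2 by 1.27, and Elovl6, a fatty acid elongase gene, by 1.97.

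Of 17 tested genes of cholinergic receptors and acetylcholine handling, 15 rose and 1 fell (adjusted p = 0.00023, and adjusted p = 0.134 with an estimated correlation). The median log2 fold change was 4.70 as fitted and 3.11 with the 4 members at 0 in vehicle set to their bound. Acetylcholinesterase, Ache, rose from 0.161 to 14.7 CPM, and the nicotinic subunit genes Chrna5 and Chrnb4 rose by 4.70 and 4.15. Of the genes of Gq and calcium signalling, the pathway downstream of Chrm1 and Chrm3, 15 of 25 rose and 4 fell without the list passing (adjusted p = 0.0952), and it passed with library totals (0.0499) and with log2(TPM + 1) (0.0435). Its members Nfatc2, Rgs2 and Stim1 rose by 3.86, 1.61 and 1.64.

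Immediate early genes, which respond within minutes to hours of receptor activation, were split, with 6 of 24 higher and 13 lower (adjusted p = 0.0941, and 0.031 lower without the filter on low counts). Egr3 rose by 2.61, Egr2 by 4.18 and Nr4a3 by 3.34, whereas Klf4 fell by 0.81. Among RAS-MAPK output genes 5 of 19 rose and 6 fell (adjusted p = 0.638), with Spry4 at 2.12 and Ccnd1 at -0.70. Of 7 tested EGFR ligand genes, 4 rose and 1 fell (adjusted p = 0.256). Tgfa rose by 1.59 and Nrg1 by 1.19, and the smaller rise of Btc (0.22, adjusted p = 0.0191) was lost without vehicle 1 (0.0981), vehicle 2 (0.0788) or bethanechol 3 (0.0582), with a replicate block (0.0611), with close pairs of libraries summed (0.176), without the filter on low counts (0.0641) and against a minimum change of 1.2-fold (0.522).

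In the Wnt target list 14 of 21 genes rose and 2 fell (adjusted p = 0.0386, and adjusted p = 0.258 with an estimated correlation). The call was lost without vehicle 2 (adjusted p = 0.0603), without bethanechol 1 (0.0636), with a replicate block (0.0511) and with close pairs of libraries summed (0.0624). Ephb2 rose from 1.34 to 52.0 CPM and Prox1 by 5.90, while Ccnd1 and Myc, both Wnt targets, fell by 0.70 and 1.68. Intestinal stem cell markers rose for 11 of 15 genes and fell for 1 (adjusted p = 0.0322, and adjusted p = 0.205 with an estimated correlation), and the call was lost with close pairs summed (0.0624). Those that rose included Lgr5 by 1.03, Prom1 by 3.21 and Slc12a2 by 1.23. Of the Notch list, 13 of 16 genes rose and 2 fell (adjusted p = 0.006, and adjusted p = 0.343 with an estimated correlation), with Dtx1 at 8.61, Notch1 at 4.67 and Notch3 at 9.10. YAP target genes were 14 up and 6 down of 21, or 7 down when adjusted over the list alone (adjusted p = 0.365), and TGF-beta and BMP targets were 8 up and 3 down of 15, or 2 down when adjusted over the list alone (adjusted p = 0.308). Serpine1, Bmp4 and Igfbp3 from these lists rose by 3.56, 2.21 and 1.58.

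Markers of specialised gut cells were measured in both groups. All 9 tested enteroendocrine markers rose (adjusted p = 0.0013, and adjusted p = 0.134 with an estimated correlation), with a median of 7.31 as fitted and 6.27 with 2 members at their bound. Chga, the chromogranin of hormone granules, rose from 0.0345 to 8.61 CPM and Scg2 from 0.0607 to 9.66 CPM. Of 11 tuft cell markers 8 rose and 2 fell (adjusted p = 0.0226, and adjusted p = 0.205 with an estimated correlation), and the call was lost with log2(TPM + 1) (0.0723) and with the library set as a term (0.053). The median of the tuft list was 5.24 as fitted and 3.09 with 2 members at their bound, and Dclk1 and Ptgs1 rose by 2.77 and 3.09. Goblet markers rose for 5 of 6 genes without passing (adjusted p = 0.051), and passed with library totals (0.0499), without the filter on low counts (0.0147), without vehicle 3 and bethanechol 1 (0.0445) and in 4 of the 6 fits that left out 1 library (0.0486 without vehicle 1, 0.0437 without vehicle 3, 0.0476 without bethanechol 1 and 0.0497 without bethanechol 3). Colonocyte markers were 9 up and 3 down of 13 (adjusted p = 0.152), with Krt20 at 5.61 and Cdhr2 at 3.19 but Car1 at -3.04. The fetal-like and injury-associated list was 7 up and 5 down of 15 (adjusted p = 0.446), and in it Clu rose from 27.4 to 219 CPM and Spp1 by 2.13. General colon epithelium markers were 7 up and 1 down of 12 (adjusted p = 0.0952, but 0.0376 with log2(TPM + 1)), and Cdh1 rose from 35.6 to 276 CPM.

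Of 15 epithelial ion transport genes 12 rose and 1 fell (adjusted p = 0.0069, and adjusted p = 0.205 with an estimated correlation), including the bicarbonate transporter gene Slc4a4 by 2.90 and Slc12a7 by 1.65, while the chloride channel gene Cftr fell by 0.72. Neurotrophic and axon guidance genes rose for 16 of 21 genes and fell for 2 (adjusted p = 0.0022, and adjusted p = 0.205 with an estimated correlation), including Ntn1 by 8.39, Slit2 by 2.00 and Sema4d by 2.30.

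Of 4 immune-related lists, 3 passed, all higher. Of 20 interferon-stimulated genes 17 rose and 2 fell (adjusted p = 0.00205, and adjusted p = 0.134 with an estimated correlation), with the RNA sensor gene Ifih1 at 3.32, Irf7 at 3.35 and Gbp2 at 4.62, whereas Stat1 fell by 0.40. Of 15 class I presentation genes 11 rose and 2 fell (adjusted p = 0.0183, and adjusted p = 0.285 with an estimated correlation), with H2-K1 at 3.02 and the peptide transporter gene Tap2 at 4.77. All 7 class II genes rose (adjusted p = 0.00365, and adjusted p = 0.134 with an estimated correlation). H2-Ab1 had 2 vehicle counts in all and 4523 with bethanechol (ratio 1830, interval 507 to 15100), and H2-DMa rose by 4.51. Chemokine, cytokine and NF-kB genes were 14 up and 4 down of 23 (adjusted p = 0.0941), with Ptgs2 at 1.23 and Tnfaip2 at -1.31.

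The lists of glycolysis, p53 targets, apoptosis and mesenchymal transition did not pass. Glycolysis and hypoxia genes were 9 up and 7 down of 21 (adjusted p = 0.923), with a median of 0.12 that was opposite in sign to the direction of the list test. Car9 rose by 3.01 and Ndrg1 fell by 1.07. Among p53 targets 7 of 17 rose and 5 fell (adjusted p = 0.98), again with a median (0.02) opposite in sign to the test, and the cell cycle inhibitor gene Cdkn1a rose from 38.9 ± 1.76 to 184.8 ± 4.75 CPM. Apoptosis regulators were 6 up and 7 down of 18 (adjusted p = 0.446), with Casp7 at 2.20 and Birc2 at -1.13. Mesenchymal transition genes were 12 up and 3 down of 21 (adjusted p = 0.0581), and passed without bethanechol 3 (0.0497), without the filter on low counts (0.0325), with log2(TPM + 1) (0.0359) and with library totals (0.0499). Fn1 rose from 236 to 2280 CPM and Snai1 by 4.76, while Vim fell by 1.33. None of the 13 mitochondrially encoded transcripts passed the gene test, and their list had an adjusted p of 0.451.

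Markers of cell types other than tumour epithelium rose with bethanechol. Of 11 fibroblast markers 10 rose and 1 fell (adjusted p = 0.0042, and adjusted p = 0.134 with an estimated correlation). Pdgfra rose from 0.847 to 138 CPM and Col1a1 from 0.532 to 80.1 CPM, but Col1a2, whose product pairs with that of Col1a1, reached 0.558 CPM, and Col3a1 fell by 0.34. All 9 tested neuron and enteric glia markers, of 11 in the list, rose (adjusted p = 0.00165, and adjusted p = 0.205 with an estimated correlation), with a median of 6.61 as fitted and 4.90 with 2 members at their bound. Ret rose from 0.18 to 84.0 CPM and Elavl3 from 0.174 to 30.2 CPM. All 6 tested smooth muscle markers, of 7 in the list, rose (adjusted p = 0.0197, and adjusted p = 0.205 with an estimated correlation), with Myh11 at 7.79 and Cnn1 at 5.43. Of 9 tested leukocyte markers, of 13 in the list, 8 rose (adjusted p = 0.0197, and adjusted p = 0.205 with an estimated correlation), at low levels: Coro1a reached 4.50 CPM, Lyz2 1.55 CPM and Laptm5 0.61 CPM. All 5 tested endothelial markers, of 8 in the list, rose (adjusted p = 0.0386, and adjusted p = 0.205 with an estimated correlation), with Kdr at 5.02. The leukocyte call was lost with log2(TPM + 1) (0.0754), and the endothelial call with log2(TPM + 1) (0.0965), without vehicle 3 and bethanechol 1 (0.0639) and with the library set as a term (0.0714).

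**Figure D3:**
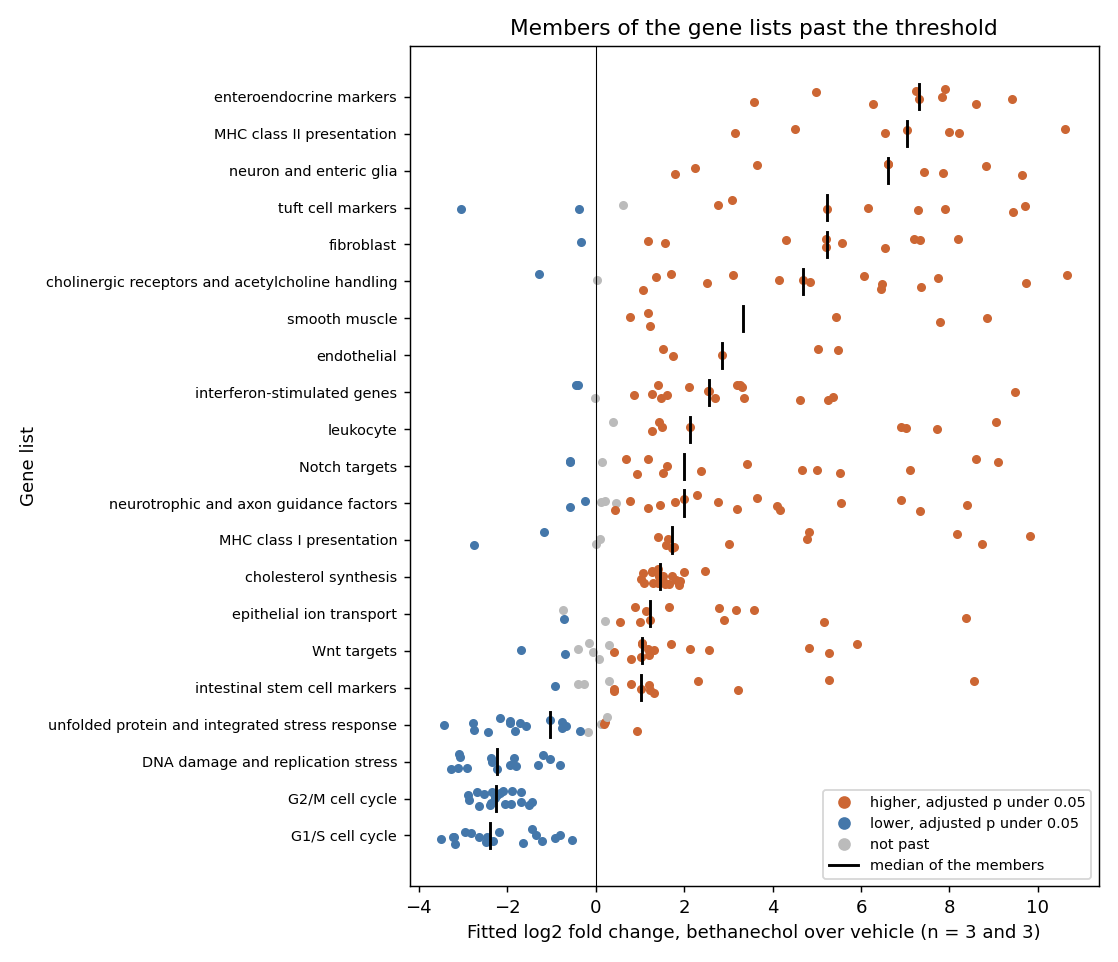
Fitted log2 fold change (x axis, n = 3 against 3) of each tested member of the 21 gene lists past the threshold; points are genes, coloured by direction where past an adjusted p of 0.05, and bars are medians. Every G1/S, G2/M and DNA damage gene lies left of 0 and every cholesterol synthesis gene right of 0; fitted values of genes at 0 in vehicle depend on the prior count.

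The libraries separated by treatment on the first principal component, which held 93.2% of the variance of log2 CPM. The second component, with 4.6%, set vehicle 3 and bethanechol 1 apart from the other 4 libraries, and these were also the libraries with 8.52% and 9.27% mitochondrial counts. Fold changes computed within each of these library sets had a Pearson's r of 0.989 across genes, which are not independent replicates. Without vehicle 3 and bethanechol 1, 13994 genes were called, 12065 of them shared with the call on all 6 libraries in the same direction. Mcm5 changed by -3.54 within the set of vehicle 3 and bethanechol 1 and by -3.33 among the other 4, and Epcam by 3.62 in both.

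**Figure D4:**
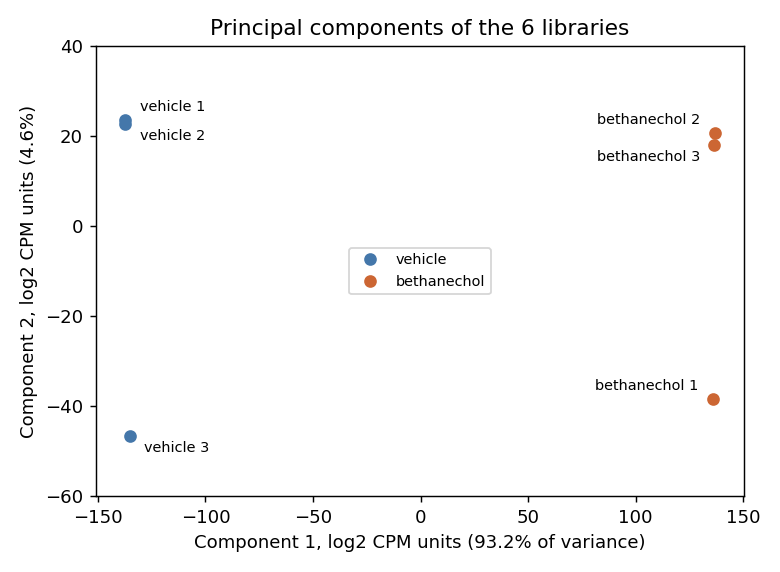
First and second principal components of log2 CPM over the tested genes for the 6 libraries, with the percent of variance on each axis. Vehicle and bethanechol libraries lie at opposite ends of the first component, and vehicle 3 and bethanechol 1 lie together at the low end of the second.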

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

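The fits without vehicle 3 and bethanechol 1, with the library set as a term, and with vehicle 1 and 2 and bethanechol 2 and 3 summed, were chosen after the result was seen. Over all alternatives between 10345 and 14151 genes passed, each within 1.5 times of 12198, and leaving out 1 library in turn gave 11360 to 12436. With scaling by library totals 11773 genes passed, 62.5% of them higher. Pairing by replicate number was examined on log2 CPM minus the group mean of each gene. In these deviations same-numbered libraries had correlations of -0.502, 0.4 and -0.564, and vehicle 3 with bethanechol 1 had 0.717. Not every library correlated best with its own number. The deviations cancel within a group and mainly follow what set vehicle 3 and bethanechol 1 apart, so they cannot decide whether same-numbered libraries were paired. With a replicate block 11102 genes and 20 lists passed, and Apc, Btc and the Wnt target list lost their calls. With these close pairs summed, 2 libraries against 2, 10735 genes and 19 lists passed, and Apc, Btc, Hbegf (adjusted p = 0.079), the Wnt target list and the stem cell list lost their calls. The number of lists past the threshold stayed between 19 and 25 in all but 1 alternative, and between 20 and 23 when 1 library was left out. The exception was the correlation estimated for each list, with which 0 of the 38 lists passed. Among lists that lost the call, the estimate was above the preset 0.01 for some, as for cholesterol synthesis (0.294). It was below 0.01 for others, as for G1/S (-0.008) and G2/M (-0.023). A higher correlation between members therefore did not account for all of these losses. That form of the test also uses fewer degrees of freedom, which raises p-values whatever the correlation. For G1/S the unadjusted camera p went from 1.48e-09 to 0.00282 although its estimate was below the preset. How much of each loss came from correlated members was not tested. Of the 8 receptor and tumour genes 5 passed, with a range of 4 to 6 over the alternatives.

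Of genes called in both fits, 7 changed direction with log2(TPM + 1), 7 with log2(TPM + 0.1) and 6 with log2(TPM + 1) without the filter. The lists that reversed passed in no fit, and the cause was not tested. The p53 targets reversed with DESeq2 size factors (adjusted p = 0.995), library totals (0.835), log2(TPM + 1) (0.722), the library set as a term (0.929), and without bethanechol 1 (0.972) or bethanechol 2 (0.99), and kept direction without vehicle 2 (0.842). RAS-MAPK output reversed with library totals (0.931) and log2(TPM + 1) (0.722), as did glycolysis and hypoxia (0.928 and 0.722). Among comparisons of named genes with their alternatives, 3524 kept direction and call, 19 lost the call (Apc, Btc, Hbegf and Trp53), 6 gained it (Kras) and 0 reversed. Most named genes were picked for large changes or small p-values in the same counts. This tally was therefore largely set by the choice of genes. For lists, 511 kept both, 32 lost the call and 17 gained it. Depth limits the muscarinic receptors in vehicle libraries, where Chrm3 rests on 2 counts and Chrm2 and Chrm5 on 0.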

Other observations

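The gene families and the matched comparison of germline genes were chosen after the results were seen. So were the share of pseudogenes and the tests on animal sex, GC content, mitochondrial transcripts, cultures, fibroblasts and leukocytes. The other tests were written down before they were run, but on patterns already seen in these data. The neuron test took as its reference Pacsin1, itself among the largest rises. A total of 12 families were tried in camera, defined by gene symbol or picked by hand, and p-values were adjusted over all of them. Because the families were picked after the values were seen, their p-values describe the shifts and do not test them. These p-values cannot be compared with those of the lists fixed beforehand. Members near the floor in vehicle libraries were tested only if bethanechol libraries expressed them, as in the lists. All 17 cytosolic aminoacyl-tRNA synthetase genes fell (adjusted p = 1.1e-07, and adjusted p = 0.0162 with an estimated correlation), with Aars from 562 ± 62.8 to 124 ± 13.0 CPM. Of 12 genes of serine and one-carbon metabolism, a list picked by hand, 10 fell and 2 rose (adjusted p = 0.00025, and adjusted p = 0.0681 with an estimated correlation), including Psph by 3.10, Shmt2 by 2.58 and Mthfd2 by 2.97 on the log2 scale. Of 77 cytosolic ribosomal protein genes 73 fell and 0 rose (median -0.94, adjusted p = 3.4e-12, and adjusted p = 0.135 with an estimated correlation), and their median stayed negative with library totals (-0.75) and log2(TPM + 1) (-0.64). Reads of these genes are shared with pseudogenes.

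Families that rose were collagen chains (36 of 39 up and 2 down, adjusted p = 0.0124 with an estimated correlation), potassium channel subunits (57 of 62 up and 1 down, 0.0124), synaptotagmins and neurofilaments (19 of 19 up, 0.0171) and keratins (22 of 31 up and 3 down, 0.0349). Krt14, a keratin of stratified epithelia, rose from 19.4 to 143 CPM. All 18 tested Wnt ligand genes rose (adjusted p = 1.3e-06, and adjusted p = 0.0968 with an estimated correlation), including Wnt5b from 0.0522 to 6.17 CPM and Wnt6 from 0.102 to 14.6 CPM. Hox genes as 1 family of 30 did not pass (adjusted p = 0.836), with 10 up and 8 down, and were divided by cluster only after this was seen. The p-values of these parts are not given, since the division followed from the values. All 10 tested Hoxc and Hoxd genes rose, with Hoxd13 going from 1 to 507 counts, whereas 0 of 20 Hoxa and Hoxb genes rose and 8 fell (median -0.17, but 0.02 with library totals and 0.12 with log2(TPM + 1)). Of 341 zinc finger Zfp genes 168 fell and 63 rose (adjusted p = 0.0004, and adjusted p = 0.0968 with an estimated correlation; median -0.26, but -0.06 with library totals and 0.04 with log2(TPM + 1)). Of 24 genes expressed in germ cells and under 1 CPM in all vehicle libraries, 1 (Brdt) reached 1 CPM in all bethanechol libraries, or 4.2%. Among other protein-coding genes, weighted to the same vehicle levels, 14.6% did (exact test stratified by vehicle level, two-sided p = 0.194). Most of these germline genes (13) had 0 vehicle counts, where other genes rarely reached 1 CPM, so a loss of repression that includes germline genes stayed open.

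The first pattern weighed was that 77.1% of tested genes differed between the groups. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 12198 genes and the highest of the others gave 0, with up to 104 genes at an unadjusted p under 0.05. Each other split mixed vehicle and bethanechol libraries, so the difference between the groups widened the spread on both sides. The 0 is therefore not an error rate for the 12198 calls. Chromosome explained 0.3% of the variance of the fold changes, and medians by chromosome lay between -0.117 (chromosome 19) and 0.376 (chromosome 18). This share could not decide on copy number differences between cultures. Rises of more than 4-fold in 3440 genes widen the variance beyond what a chromosome gain or loss would move, and changes of part of a chromosome were not tested. Animals of different sex were argued against by the Y-linked Ddx3y, Kdm5d and Uty, which had at least 447 counts in all 6 libraries. Eif2s3y, another Y-linked gene, had at most 2 counts in any library of either group. Cultures or tumour lines that differed in something other than the drug cannot be told apart from the treatment, because 0 of the 6 libraries have a label naming a culture, line or passage. Such a difference could account for part or all of the pattern, and the drug itself remains an open explanation. The vehicle libraries held 10 counts of Chrm1, 2 of Chrm3 and 21 of Chrm4 in all. Whether the drug could act through receptors at such transcript levels was not tested.

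The second pattern was that vehicle 3 and bethanechol 1 deviated together from the other libraries of their groups, with a Pearson's r of 0.717 across genes. More mitochondrial counts, 8.52% and 9.27% in these libraries, would dilute nuclear genes alike and were argued against as the whole cause, since nuclear genes were spread 4.32 and 4.33 times as widely in these libraries as between the other 2 of each group. GC content was argued against, since r was 0.716 after its trend was removed and 0.718 before, a test chosen because the rank correlations of the deviations with GC content (-0.164 and -0.149) did not decide. For reads assigned differently between genes and their pseudogenes, r was taken over 14088 nuclear protein-coding genes and was 0.568. That set keeps the protein-coding genes that share reads with pseudogenes. The value therefore could not decide whether such assignment was the whole cause. For the 100 genes that deviated most, however, 80% were pseudogenes, predicted or mitochondrial genes against 5.7% of tested genes, which is consistent with such assignment, as with Gm28661 (-13.97 and -12.22 on the log2 scale) and Rpl19-ps11 (7.55 and 8.07). What set these libraries apart otherwise stayed open, no batch is named in the labels, and no biological explanation was tested.

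The third pattern was the rise of markers of other cell types in an epithelial culture, for which no sort or gate is described. Fibroblasts were argued against only as the main source of the Col1a1 level, and a small share of fibroblasts stayed open. The median of 8 abundant fibroblast transcripts was 9.23% of the Col1a1 level, which lay between the limits set. Of the 8, 4 were under 5% of it, including Col1a2 (0.558 CPM), Dcn (0.733 CPM) and Lum (0.0557 CPM). Sparc and Col6a1, however, reached 40.4 and 138 CPM. The argument rests on the count of low transcripts, which was added after the levels were seen. Leukocytes were likewise argued against only as the main source of the H2-Ab1 level, with a median of 3.88% of it over 10 transcripts, 6 of them under 5%, and Tyrobp at 0. A small share of leukocytes stayed open, since Coro1a, Lcp1 and Cd52 were at 4.5, 5.18 and 2.66 CPM with bethanechol. Fcer1g and Ctss were at 0.14 and 0.0129 CPM. Neurons stayed open, since the median of 10 abundant neuron transcripts was 91.6% of the Pacsin1 level, with Uchl1 at 253, Stmn2 at 70.2 and Elavl4 at 0.671 CPM, 3 of the 10 being over 1 CPM in vehicle libraries. Neurons in the cultures or tumour cells that express neuronal genes could each give these values.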
